A study of Mus musculus with 7 samples.

How the data were processed

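The data are RNA-seq libraries of autoreactive CD8 T cells from NOD/ShiLtJ mice, a strain that develops autoimmune diabetes spontaneously. Per the labels, the cells were sorted from 11-week-old females as CD45.1+ CD8+ CD4- CD19- CD11c- CD44+ cells that bound a tetramer carrying a peptide of IGRP, a protein of pancreatic beta cells. There were 4 libraries from spleen, each of 1 mouse, and 3 libraries from pancreatic islets, each pooled from several mice. Spleen and islet libraries therefore differ in pooling as well as in tissue, and the spread between islet libraries is a spread between pools. Libraries were made from polyadenylated RNA by the SMART-seq method, per the labels' protocols, which amplifies full-length cDNA and adds no molecular identifiers. The number of cells per library and the strandedness of the reads are not given in the sources used here.

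The submitters' processing notes name TopHat2 2.1.1, Cufflinks 2.2.2, Cuffdiff and the genome build mm9, without giving the role of each. The deposited table has the layout of Cuffdiff output per replicate and holds 24312 genes, known by symbol, in 7 libraries. The authors deposited an estimated count of fragments per gene and library, and 1.253% of these 170184 estimated counts were not whole. They were rounded to whole numbers before any count test. The table also gives the authors' scaled fragment value, a signal scaled between libraries, and the authors' FPKM, fragments per kilobase of transcript scaled to library depth. The internally and externally scaled values were equal in every row. The table marks 2 genes with a status other than OK in at least 1 library. The table gives each library's tissue and a replicate index that starts at 0, and does not say which labelled sample an index stands for. Libraries are therefore known by tissue only. They are numbered here from 1 in the order of that index, and these numbers are not tied to the numbers in the labels. Coordinates are not used here because the annotation at hand is of another build than mm9.

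Totals ran from 4786776 fragments in spleen library 3 to 12543355 in spleen library 2. A count of 3 fragments was used as the floor for a gene at 0 in a library. With totals taken over the tested genes and scaled by TMM, as described below, it corresponds to 0.235 to 0.727 CPM. CPM is the share of a library's fragments scaled to a common total. Floors cover counting error only, because amplified fragments without molecular identifiers are not independent molecules. Reads shared between near-identical genes cannot be assigned with certainty, which concerns the ribosomal protein genes with their many pseudogenes and the pair Hspa1a and Hspa1b. Overlapping and antisense genes cannot be separated without strand.

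Genes were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test with robust estimation, after filterByExpr with the tissue as group and TMM scaling. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and 9873 genes were tested. Levels are CPM with TMM scaling, given as mean ± SD over the libraries of a tissue. Fold changes are on the log2 scale, positive for higher in islet. Their standard error was obtained by dividing the size of the fold change by the square root of the test's F statistic. It therefore restates the test and is no separate measure of spread. Folds against a tissue with no fragment in any library are lower bounds, computed against the mean over libraries of a floor of 3 fragments per library. Before the data were examined, 32 gene lists, the design, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested members, 24 in all, were tested with camera in limma 3.58.1, with the correlation between genes preset to 0.01 and adjustment over lists. List members were also counted with adjustment over the list alone. The number of genes per library was compared by an exact two-sided permutation test over the 35 splits of the libraries, whose smallest p is 0.0571.

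The rule named the 12 genes per direction with the largest change among those called, with a mean of at least 20 CPM over both tissues and no overlap between spleen and islet libraries. It further named up to 4 called members and the 2 most abundant other members of each list, any member of 5 lists (sort gate and lineage, inhibitory receptors, memory, residency, recirculation), the negative gate markers, and the 2 most abundant markers of each other cell type. The first part of the rule named 0 genes with all 7 libraries. It was applied instead to the fit without spleen library 1, a choice made after the data had been seen, where 38 higher and 24 lower genes were eligible.

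A planned fit with the labels' replicate number as a block was not run, because the table carries no such number. Alternatives were DESeq2 1.42.0, limma-voom, other scalings, the authors' scaled values, other filters, limma on log2(FPKM + 1) with other pseudocounts of 0.1 and 5, no genes of other cell types, genes with status OK, a fold threshold of 1.5, each library left out in turn, an estimated correlation in camera, fry, and lists without shared members. DESeq2 without spleen library 1 and limma with library weights were added after the data had been seen. The procedure was tested on simulated data for the islet against spleen comparison, drawn from the means and library sizes measured here, with genes changed by known folds. At a dispersion of 0.05, edgeR recovered 74% of 2-fold and 100% of 4-fold changes among 9828 genes, with 9 false calls. At the dispersions fitted to these libraries, edgeR recovered 4.08% of 4-fold and 17.4% of 16-fold changes among 9432 genes, with 3 false calls. In the same simulation DESeq2 recovered 10.2% and 45.7%, with 96 false calls. Those dispersions were edgeR's own, estimated with spleen library 1 included, and were applied to all 7 libraries alike. Figures were drawn with matplotlib.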

Results

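IGRP-specific CD44+ CD8 T cells were profiled in the spleen and in the pancreatic islets of female NOD mice aged 11 weeks. The comparison asks how cells of 1 antigen specificity differ in expression between a lymphoid organ and the tissue that holds their antigen. The 4 spleen libraries were single mice, and the 3 islet libraries were pools of several mice. Spleen libraries held 4786776 to 12543355 fragments and islet libraries 8418222 to 10012229. Islet libraries contained 11948 ± 324 genes with at least 1 fragment and spleen libraries 10229 ± 1935 (exact two-sided permutation p = 0.0571, n = 3 and n = 4, the smallest p that 35 splits allow). The difference was 1719 genes, or 767 without spleen library 1. Spleen library 1 contained 7373 genes from 5356782 fragments, and spleen library 3 contained 10702 genes from 4786776 fragments. Correlations of log2 CPM across genes, which are not independent replicates, were 0.489 to 0.493 between spleen library 1 and the other spleen libraries. They were 0.676 to 0.684 among the other spleen libraries and 0.791 to 0.824 among islet libraries. Between tissues, without spleen library 1, they were 0.602 to 0.689, which overlaps the range among those spleen libraries.

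**Figure D1:**
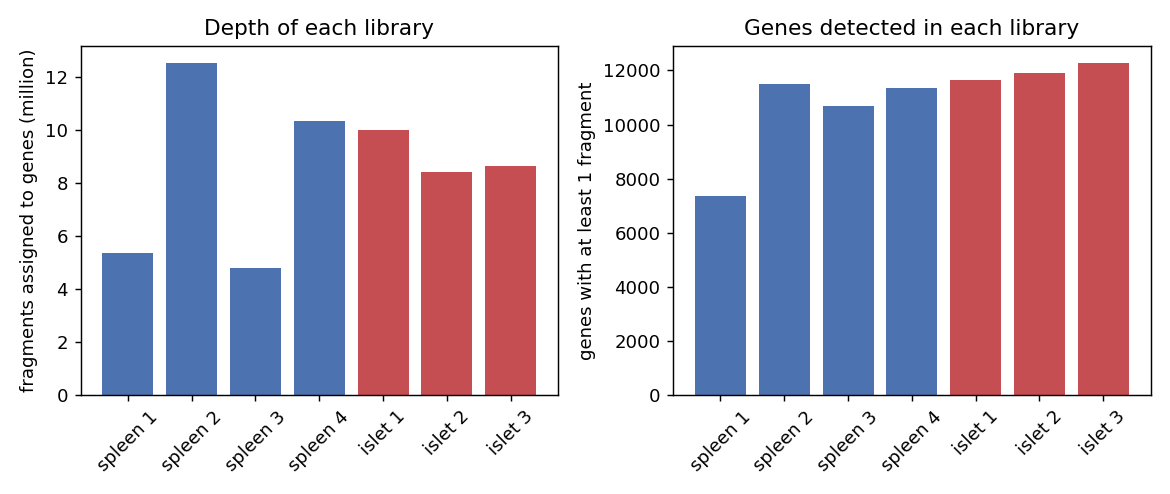
Fragments assigned to genes (left) and number of genes with at least 1 fragment (right) for each of the 4 spleen (blue) and 3 islet (red) libraries. Spleen library 1 holds 7373 genes, below the 10702 to 12292 genes of the other 6 libraries.

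Cell division genes were higher in islet cells, and transcripts of lymphoid recirculation and of naive and memory cells were lower. Inhibitory receptor genes were higher with camera's preset correlation, and the call was lost with an estimated correlation (adjusted p = 0.0968). All 50 cell cycle genes had a higher fitted level in islet than in spleen. Gzmb, which encodes the cytotoxic protease granzyme B, had no fragment in any spleen library and reached 188 ± 147 CPM in islet (SD, n = 3), at least 391-fold higher. Without islet library 1 it averaged 114 ± 101 CPM, at least 237-fold higher. Ccr7, the chemokine receptor that guides T cells into lymph nodes, averaged 634 ± 235 CPM in spleen (SD, n = 4) and 39.9 ± 18.0 CPM in islet (SD, n = 3). With all 7 libraries, edgeR called 0 genes higher and 0 lower, with 522 higher and 331 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.0729. DESeq2 called 318 higher and 83 lower on the same counts, and limma-voom 314 and 92. Without spleen library 1, edgeR called 55 genes higher and 25 lower among 9802 tested. Of these 80 genes, 65 were also called in the same direction by DESeq2 on all 7 libraries, 6 of which both fits share. Over all 9873 tested genes, 17.4% had no overlap between tissues, where chance gives 5.71% on average over splits. Genes vary together across the same libraries, so a single split can lie far from that average. The contrast is no test. Camera called 4 of the 24 tested lists higher and 5 lower, and 3 of these 9 calls held with an estimated correlation between genes. Over their alternatives the adjusted p of the called lists was highest with that estimate, except for early and heat shock genes (0.283 with fry) and cytokine receptor genes (0.220 without shared members).

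The cell cycle list was higher in islet, with a median log2 fold change of 4.25 (camera in edgeR, adjusted p = 1.44e-38, and adjusted p = 0.0116 with an estimated correlation). Adjusted over the list alone, 34 of the 50 members rose and 0 fell, with 22 rising without islet library 2 and 20 without islet library 3. Over all genes tested, 0 members were called with all 7 libraries, 17 without spleen library 1, and 28 by DESeq2. Of these members, 6 had no fragment in any spleen library. Their bounds all lie above the median, so setting them to their bound could not move it from 4.25. Without spleen library 3 the median was 5.24. Ccnb1, a mitotic cyclin, averaged 166 ± 84.1 CPM in islet (SD, n = 3) against 1 fragment in the 4 spleen libraries together. Cdc45, a part of the replicative helicase, averaged 120 ± 30.7 CPM against 1 fragment. The mitotic kinase genes Aurka and Aurkb had no fragment in spleen and were at least 86.7-fold and 148-fold higher in islet. Tpx2, a spindle assembly factor, averaged 84.4 ± 13.2 CPM in islet and 0.179 ± 0.179 CPM in spleen (0.101 CPM without spleen library 3). The most abundant members were already present in spleen. Hmgb2 averaged 332 ± 196 CPM in spleen and 1236 ± 381 CPM in islet, and Mcm6, a subunit of the replicative helicase, 79.3 ± 100.4 and 574 ± 215 CPM, with 31.3 ± 36.4 CPM in spleen without spleen library 2. Outside the list, Rad51, the recombinase of DNA repair, Cdca5, a cohesion factor, and Fignl1 rose in the fit without spleen library 1. Rad51 and Cdca5 had no fragment in spleen and were at least 214-fold and 93.6-fold higher in islet, where Cdca5 averaged 45.2 CPM. Without islet library 3, Cdca5 averaged 25.3 ± 8.55 CPM, at least 52.5-fold higher. Cenpp and Med20 rose in that fit too, but spleen library 1 held 40.5 and 44.1 CPM of them, and with all 7 libraries neither passed (edgeR, adjusted p = 0.944 and 0.928).

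The list of inhibitory receptors and exhaustion-associated regulators was higher in islet, with 20 of 23 tested members higher and a median log2 fold change of 1.45 (camera in edgeR, adjusted p = 1.42e-06). The call was lost with an estimated correlation (adjusted p = 0.0968). The median was 2.09 without spleen library 1 and 2.32 without spleen library 3, and 1.20 to 3.13 over all alternatives. Of its members, 7 rose when adjusted over the list alone: Havcr2, Pdcd1, Cd200, Tigit, Cd101, Tox2 and Cd244. This count was 13 without spleen library 1, 5 without spleen library 2 or 3, 1 without spleen library 4, islet library 2 or islet library 3, and 0 without islet library 1. Havcr2 was also called by edgeR over all genes without spleen library 1 (adjusted p = 0.0313, with 2.99e-11 to 0.289 over its alternatives), with 1 fragment in the spleen libraries and 54.5 ± 36.0 CPM in islet (SD, n = 3), or 33.7 ± 1.98 CPM without islet library 1. Pdcd1, the gene of the receptor PD-1, averaged 6.56 ± 7.75 CPM in spleen (3.33 ± 5.25 CPM without spleen library 3) and 344 ± 156 CPM in islet. Tigit averaged 81.1 ± 38.1 and 336 ± 92.4 CPM. Lag3 and Entpd1, with log2 fold changes of 3.77 and 3.16, passed over the list alone without spleen library 1 but not with all 7 libraries. Tox, a regulator of exhausted T cells, had a log2 fold change of 1.06 ± 0.53 (SE) and did not pass.

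Of the cytotoxic and effector molecules, Gzmb rose and Gzmm fell when adjusted over the list alone. Gzmb also passed with each library left out in turn, while Gzmm did not pass without islet library 1, 2 or 3. The list as a whole was not called (camera adjusted p = 0.639, 16 members tested). Nkg7, a component of cytotoxic granules, had 4886 ± 1182 CPM in spleen and 5228 ± 1287 CPM in islet, a difference below the spread between libraries. The terminal effector list was not called either (adjusted p = 0.515), with a median of 0.13 and a mean of -0.12 that differ in sign.

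Genes of naive, stem-like and memory T cells were lower in islet, with 19 of 23 tested members lower and a median log2 fold change of -2.16 (camera in edgeR, adjusted p = 1.82e-10, and adjusted p = 0.0370 with an estimated correlation). Libraries overlapped between tissues in the mean log2 CPM of this list (exact two-sided permutation p = 0.114). It was 4.55 in islet library 2 and 4.53 in spleen library 1. Of its members, 5 fell when adjusted over the list alone: Ccr7, Lef1, Il7r, Igfbp4 and Satb1. This count was 7 without spleen library 1, 4 without islet library 2, and 2 without spleen library 2, islet library 1 or islet library 3, and Ccr7 passed with each library left out in turn. Il7r, the receptor for interleukin-7, averaged 292 ± 53.3 CPM in spleen and 8.91 ± 11.7 CPM in islet (2.24 ± 3.06 CPM without islet library 2). Lef1, a transcription factor of naive T cells, averaged 298 ± 191 and 49.0 ± 3.81 CPM. Tcf7, its relative, had 268 ± 137 and 131 ± 56.1 CPM and did not pass. Sell, the adhesion receptor L-selectin, had 270.2 ± 262 and 23.4 ± 39.0 CPM (140.0 ± 33.7 CPM in spleen without spleen library 1, and 0.906 ± 1.06 CPM in islet without islet library 3). It did not pass with all 7 libraries but fell over the list alone without islet library 3.

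The recirculation list, genes of lymphoid homing and tissue egress, was also lower, with 17 of 20 tested members lower and a median log2 fold change of -1.12 (camera in edgeR, adjusted p = 2.59e-09, and adjusted p = 0.0168 with an estimated correlation). Ccr7 and Sell belong to both lists. Ccr7, S1pr1, Klf2 and Sidt1 fell when adjusted over the list alone, and the first 3 did so with each library left out in turn. Sidt1 did not pass without spleen library 2 or 3 or any 1 of the islet libraries. Without spleen library 1, 7 members fell and 1 rose over the list alone, and edgeR called Ccr7, S1pr1 and Klf2 over all genes. S1pr1, the receptor that directs exit from tissues, averaged 536 ± 128 CPM in spleen and 46.5 ± 18.2 CPM in islet. Klf2, the transcription factor that activates S1pr1, averaged 559 ± 460 and 48.3 ± 30.8 CPM, with 330.2 ± 51.8 CPM in spleen without spleen library 1 and 31.6 ± 14.8 CPM in islet without islet library 3. The residency list was higher with a median of 1.33 (camera in edgeR, adjusted p = 0.0419), but not with an estimated correlation (adjusted p = 0.223). It was not called when spleen library 3, spleen library 4, islet library 1 or islet library 2 was left out, with medians of 1.25, 1.40, 1.01 and 1.04. Itga1, an integrin chain of resident T cells, rose when adjusted over the list alone, and Cd69, which holds T cells in tissue and also marks recent activation, fell. The number rising was 7 without spleen library 1, 4 without spleen library 2, 2 without spleen library 3 or islet library 1, and 0 without spleen library 4, islet library 2 or islet library 3. Cd69 did not pass without spleen library 4 or islet library 3. Itga1 had no fragment in spleen and 6.80 ± 3.85 CPM in islet, and Cd69 averaged 1257 ± 348 CPM in spleen and 366 ± 163 CPM in islet. Cxcr6, a chemokine receptor of tissue T cells, had 24.0 ± 27.5 and 544 ± 137 CPM, with 12.54 ± 18.6 CPM in spleen without spleen library 4, and passed over the list alone without spleen library 1, but not with all 7 libraries.

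**Figure D2:**
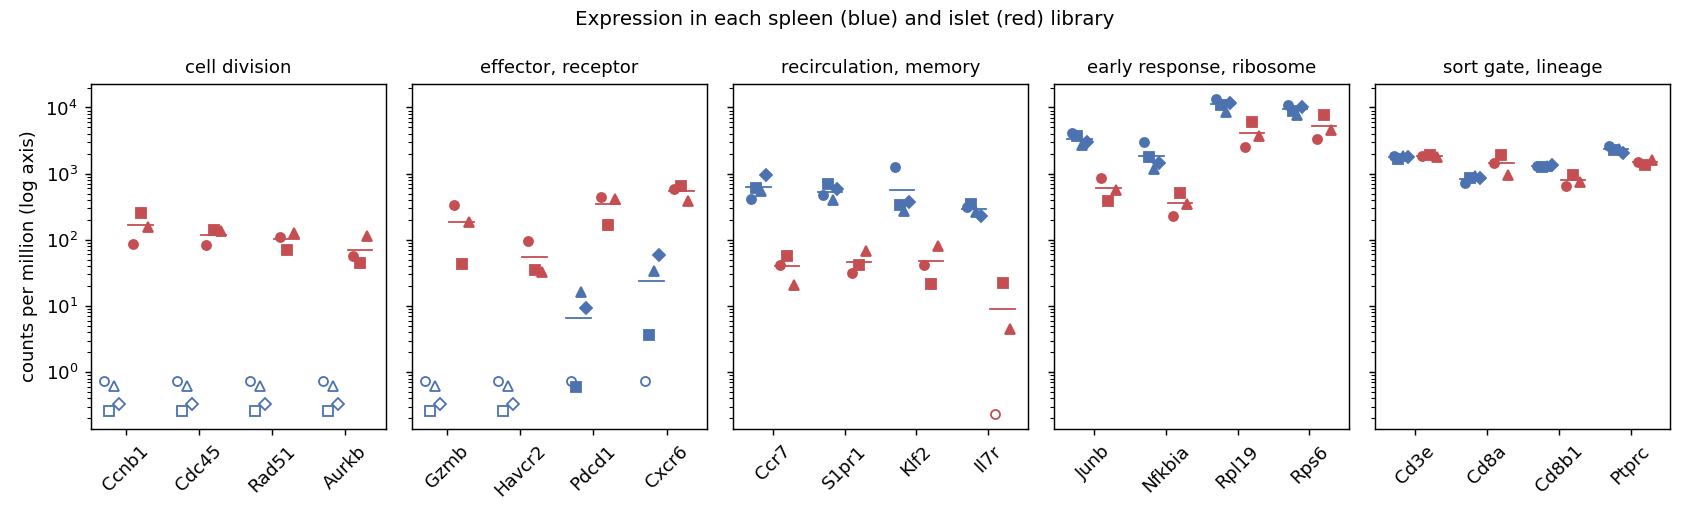
CPM on a log axis in each spleen (blue) and islet (red) library for 20 genes. The marker shape tells the libraries of a tissue apart and pairs none of them, horizontal lines are group means, and open markers lie below the floor of 3 fragments and are drawn at it. Rad51 and Gzmb lie under the floor in all 4 spleen libraries, and Cd3e is at 1799 CPM in spleen and 1855 CPM in islet on average.

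Ribosomal protein genes were lower in islet in all 41 cases, with a median log2 fold change of -1.25 (camera in edgeR, adjusted p = 1.62e-27), and 36 fell when adjusted over the list alone (23 without islet library 3). With an estimated correlation the call was lost (adjusted p = 0.242). Rpl19 averaged 11100.4 ± 1978 CPM in spleen and 4077 ± 1734 CPM in islet. Immediate early and heat shock genes, which tissue digestion can induce, were lower as a list by camera, with a median of -0.91 over 29 members (camera in edgeR, adjusted p = 0.000446, and adjusted p = 0.183 with an estimated correlation). The mean was -0.20, and limma on FPKM gave medians of -0.25 to -0.15. The mean log2 CPM of the list was 6.73 in spleen and 6.67 in islet (exact two-sided permutation p = 0.971). Its members went both ways. Adjusted over the list alone, the early genes Junb, Ier2, Ier5 and Zfp36, the feedback inhibitor Nfkbia and the antiproliferative Btg1 fell, while the heat shock genes Hspa1a, Hspa1b and Hspa8 rose. Without spleen library 1, 10 members fell and 4 rose. Ier5 passed in that fit but in none of the other fits with 1 library left out, and Hspa8 did not pass without spleen library 2 or islet library 1. Junb averaged 3395 ± 657 CPM in spleen and 606 ± 241 CPM in islet, and Hspa8 2439 ± 528 and 5400.3 ± 2485 CPM. Cholesterol and fatty acid genes were higher, with a median of 1.96 over 22 members (camera in edgeR, adjusted p = 0.00106, and adjusted p = 0.542 with an estimated correlation), and 0 members passed when adjusted over the list alone, or 2 without spleen library 4. The median ranged from 0.74 to 3.04 over all alternatives. In spleen library 1 the mean of this list was -0.73 log2 CPM, against a spleen mean of 2.41. Cytokine receptor genes were lower, with a median of -0.88 over 19 members (camera in edgeR, adjusted p = 0.00397, and adjusted p = 0.0968 with an estimated correlation). Over the list alone, 0 members passed, or 3 without spleen library 1 and 1 without islet library 1 or 2, all lower. The median was -0.40 without spleen library 1 and -0.50 without spleen library 3. Il2rg, the common gamma chain, had 1669 ± 211 CPM in spleen and 910 ± 252 CPM in islet.

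The remaining genes that the rule named from the fit without spleen library 1 included Shcbp1, a member of the cell cycle list, among those higher. Among those lower they were Rgcc, Nsg2, Znrf3, Txnip, Sgk1, Rabac1 and Hcst. Txnip, an inhibitor of glucose uptake, averaged 320 ± 317 CPM in spleen, or 162 ± 27.2 CPM without spleen library 1, and 18.8 CPM in islet, with 17.5 to 21.4 CPM over libraries. Sgk1, a kinase regulated by glucocorticoids, averaged 510 ± 242 and 53.5 ± 25.7 CPM, and Hcst, which encodes an adaptor of NK receptors, 439.5 ± 91.5 and 79.9 ± 29.7 CPM. In this fit Txnip had a log2 fold change of -3.09 ± 0.43 (SE, adjusted p = 0.0239, with 2.04e-09 to 0.289 over its alternatives).

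**Figure D3:**
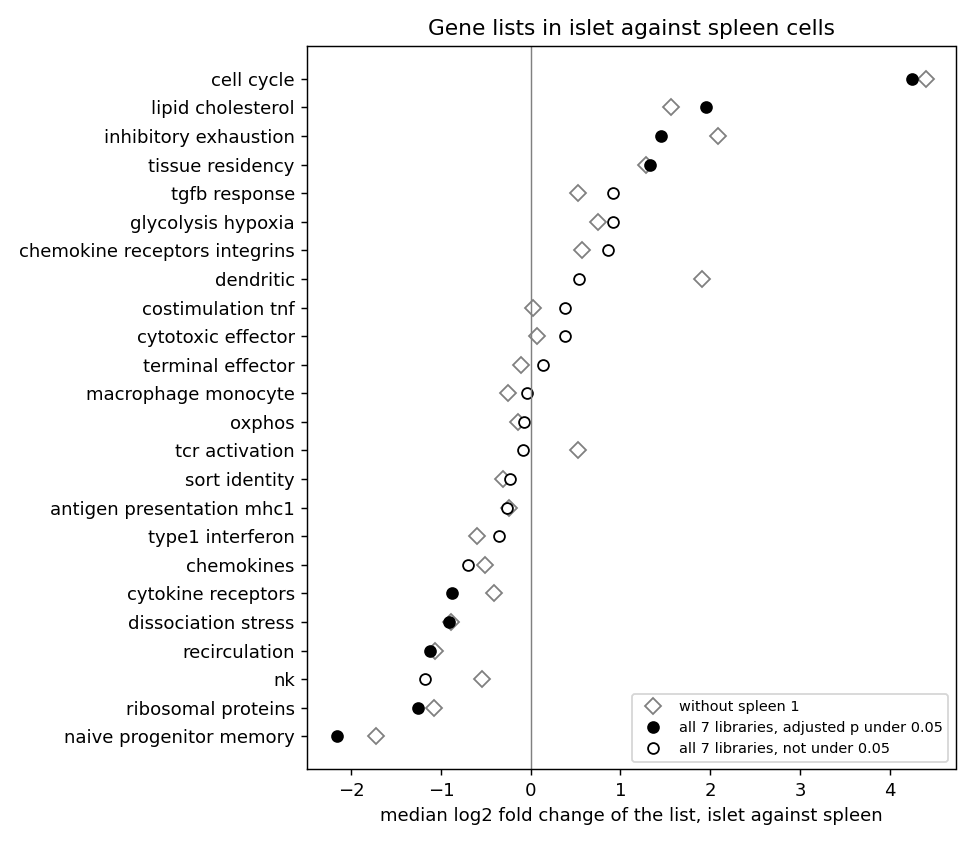
Median log2 fold change, islet against spleen, of the 24 tested gene lists with all 7 libraries (circles, filled where camera's adjusted p was under 0.05) and without spleen library 1 (grey diamonds). The cell cycle list lies at 4.25 and 4.40, and the naive and memory list at -2.16 and -1.72.

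Genes of the sort gate and T cell lineage were not called as a list (camera adjusted p = 0.137), except with limma-voom and limma with library weights (adjusted p = 0.0173 and 0.0293, with 0.0173 to 0.551 over its alternatives). Cd3e had 1799 ± 85.4 CPM in spleen and 1855 ± 47.3 CPM in islet. Cd8a had 837 ± 89.5 and 1429 ± 481 CPM, Cd8b1 1307 ± 33.1 and 790 ± 159 CPM, and Ptprc 2339 ± 248 and 1476 ± 131 CPM, none of which passed. Cd3d had 2335 ± 321 and 1083 ± 360 CPM and passed over the list alone with all 7 libraries, but with 1 library left out it passed without islet library 2 and in none of the other 6 fits. Cd44, selected for in the sort, had 45.1 ± 39.3 and 131 ± 17.3 CPM, with a log2 fold change of 1.54, and did not pass. With spleen library 1 left out, it had 25.9 ± 9.68 CPM in spleen and a log2 fold change of 2.35, and rose when adjusted over the list alone. Cd19 had no fragment in any library, Cd4 had 2 fragments in spleen and 8 in islet libraries, and Itgax had 13.5 CPM in spleen library 4 and at most 0.828 CPM elsewhere.

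RNA of other pancreatic and immune cells was found in islet libraries, unevenly between them, and some of these markers in single spleen libraries. Ins2, an insulin gene, had no fragment in spleen and 1.02, 27.6 and 15.6 CPM in islet libraries 1, 2 and 3, and it passed when adjusted over the list of beta cell genes alone. Without islet library 1, Ins1, which was not tested with all 7 libraries, rose over that list too. In that fit 8 acinar and 2 other endocrine genes rose over their own lists. With all 7 libraries 0 of each rose, but only 2 acinar and 0 other endocrine genes passed the filter there. Leaving out an islet library lowers the number of libraries the filter asks for. Genes then enter through the remaining islet libraries where they are high, so these counts are not comparable. The acinar number was 2 without islet library 3 and 1 without spleen library 3. Cela1, which encodes an elastase, had 48.1, 85.9 and 49.7 CPM in islet and 19.9 CPM in spleen library 3. Other markers on these lists were as high or higher in a spleen library. Cela2a had 188 fragments in spleen library 2 and 0, 175 and 152 in islet libraries. Cel had 112 in spleen library 3 and 0, 73 and 2 in islet libraries. Ero1lb, on the beta cell list, had 972 in spleen library 4 and 96, 14 and 2 in islet libraries. In islet library 1, where Cela1 had 614 fragments, the exocrine genes Clps, Cpa1, Ctrb1 and Pnlip had 0, against 402, 112, 277 and 157 fragments in islet library 2. Other exocrine genes were present in islet library 1. Ctrc had 37 fragments there and 19 in islet library 2, and 2210010C04Rik 31 and 174. Cpa1, Ctrb1, Pnlip, Ctrc and 2210010C04Rik were chosen after their values had been seen. Apoe, an abundant macrophage transcript, had 0.470, 54.8 and 133 CPM in islet. Cd74, expressed by antigen-presenting cells, had 2.27, 246 and 136 CPM in islet and 22.5 to 64.8 CPM in spleen. Jchain, a plasma cell transcript, had 1413 CPM in islet library 2 and 170 CPM in spleen library 3. The macrophage, dendritic cell and NK cell lists were not called with all 7 libraries (camera adjusted p = 0.722, 0.722 and 0.515). Without islet library 1 the macrophage list was higher in islet (camera in edgeR, adjusted p = 0.0196, with 0.0196 to 0.962 over its alternatives, median 0.73). In the other direction, spleen library 1 held H2-Eb1 at 418 CPM, H2-Aa at 360 CPM and the erythroid gene Alas2 at 208 CPM. The log2 fold changes of H2-Aa and H2-Eb1 were -1.43 and -1.96 with all 7 libraries and 2.19 and 1.88 without spleen library 1, and neither passed.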

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

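The tests of depth and of a wrong label in this part were chosen after the result had been seen. Of 119 measures examined for a spleen library far from the other 3, 27 met the criterion. Chance gives about 5% for measures chosen blindly, but some of these were genes named from the fit without spleen library 1, and a gene with no fragment in 3 of the libraries meets the criterion by construction. The count is therefore no evidence of an excess, in spleen library 1 or overall. The islet group of 3 libraries was too small to examine.

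Spleen library 1 had 4545 genes with at least 10 fragments, and 7247 genes after all libraries were thinned to the total of the smallest. Its mean log2 CPM met the criterion, on the low side, for the lists of glycolysis (2.66), respiratory chain (6.38) and lipid genes (-0.73). These lists were not alone. Spleen library 1 had the lowest mean of the spleen libraries for every list scored except ribosomal protein, dendritic cell and cytokine receptor genes. Its levels were high for Klf2 (1246 CPM), Txnip (794 CPM), Sell (661 CPM), Lef1 (584 CPM), Satb1 (548 CPM), Gzmm (261 CPM), Stmn1 (191 CPM), H2-Eb1 (418 CPM), H2-Aa (360.3 CPM), Alas2 (208 CPM), Med20 (44.1 CPM) and Cenpp (40.5 CPM), and it alone held a fragment of Havcr2 among the spleen libraries (0.242 CPM). Depth alone argues poorly for this: after thinning, the other spleen libraries kept 10531 to 10702 genes against 7247. The cell cycle list cannot decide on an islet library under a spleen label. Its mean log2 CPM in spleen library 1 was 0.39, against 0.88 to 1.98 in the other spleen libraries and 6.60 to 6.87 in islet libraries. Genes without fragments lower that mean. Ccnb2, Tk1 and Ube2c had 1838, 1594 and 1391 fragments there, against at most 124, 227 and 90 in another spleen library. Cdk1, Rrm2 and Top2a had 0. Correlations of spleen library 1 were 0.395 to 0.446 with islet libraries and 0.489 to 0.493 with the other spleen libraries. Of 3482 genes at 20 CPM or more in each of the other 3 spleen libraries, 690 had no fragment in spleen library 1. For each other spleen library it was 3 of 2014 to 2026 genes, smaller sets that require 20 CPM in spleen library 1 too. Random loss of transcripts before amplification would give such a count. The count partly restates the low gene number of that library, so it does not decide the cause. Fewer or damaged cells in that sort could give this pattern, and cell numbers are not given in the sources used here. A difference between mice was not tested.

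The other values were single libraries with a level the remaining spleen libraries lacked or nearly lacked. Cdc45 was at 0.206 CPM, Hspa1b at 0.411 CPM, Cela1 at 19.9 CPM and Jchain at 170 CPM in spleen library 3. Ccnb1 was at 0.109 CPM, Apoe at 5.67 CPM and Itgax at 13.5 CPM in spleen library 4. Il10 was at 0.172 CPM and Ctrb1 at 0.0858 CPM in spleen library 2. For Ccnb1, Cdc45, Ctrb1 and Havcr2 the value was 1 fragment and for Il10 and Hspa1b 2 fragments, under the floor of 3 fragments.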

How the results depend on the processing

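The fit without spleen library 1 was planned as one of the fits that leave out each library, while DESeq2 without that library and limma with library weights were chosen after the data had been seen. The count of called genes depended on the tool: against 0 higher and 0 lower in edgeR, DESeq2 gave 318 and 83, limma-voom 314 and 92, limma with library weights 314 and 135, and DESeq2 without spleen library 1 425 and 206. Limma on log2(FPKM + 1) gave 293 and 45, with a pseudocount of 0.1 229 and 27, with 5 187 and 40, and without a filter 124 and 7. Without a filter on low counts, edgeR gave 11 and 23. With 1 library left out, edgeR gave 0 to 55 higher and 0 to 25 lower, and the upper values were reached without spleen library 1, where the common dispersion was 0.792 against 1.40. The other scalings, the authors' scaled values, the stricter filter, genes with status OK, no genes of other cells and the fold threshold gave 0 and 0 in edgeR. In 711 genes DESeq2 gave no adjusted p. In the simulation at fitted dispersions, edgeR recovered few changes and DESeq2 made more false calls. That simulation gave all 7 libraries edgeR's own dispersions, estimated with spleen library 1 included. It therefore does not measure the error of either tool in these data, and the true number lies open.

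No paired analysis was possible because the deposited table gives each library's tissue but does not tie its replicate index to the numbers in the labels.

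The cell cycle, naive and memory, and recirculation lists stayed called in all 26 alternatives, with medians of 2.45 to 6.64, -2.48 to -0.77 and -1.66 to -0.71. An estimated correlation left 3 called lists and fry 5. The first ended the calls of ribosomal protein (-1.25), inhibitory receptor (1.45), early and heat shock (-0.91), lipid (1.96), cytokine receptor (-0.88) and residency genes (1.33). Fry ended those of ribosomal protein, early and heat shock, lipid and cytokine receptor genes. Both leave the medians as they were. The residency call was also lost with limma-voom (1.67), upper-quartile scaling (1.22), the stricter filter (1.20), FPKM with pseudocounts 1 (1.41) and 0.1 (1.79), no shared members (1.27), and 4 of the fits with 1 library left out (medians of 1.01 to 1.44 over all 7 such fits). The cytokine receptor call was also lost without shared members (-0.34) and in DESeq2 without spleen library 1 (-0.44). Some lists not called with all 7 libraries were called in alternatives, with the same direction of the test. Glycolysis genes were called in 8 of 26: without spleen library 1 (0.74), without it in DESeq2 (0.71), without a filter (0.94), with the stricter filter (1.13), with library weights (0.98), and in limma on FPKM with pseudocounts 0.1 (1.45), 5 (0.65) and 1 without a filter (0.60). MHC class I genes were called with limma-voom (-0.12), with library weights (-0.25) and without islet library 1 (-0.26). Respiratory chain genes were called with limma-voom (-0.13) and without islet library 2 (-0.40), and sort gate and lineage genes with limma-voom (-0.10) and library weights (-0.40). The cause was not tested.

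Of the genes named in the text, Cd3e, Nkg7, Cd74, Jchain, H2-Aa and H2-Eb1 changed sign, with no call in the alternatives that reversed them. Cd3e was at -0.045 in DESeq2 and -0.045 with its size factors in edgeR, and -0.19 with upper-quartile scaling. Nkg7 was at -0.12 with upper-quartile scaling, -0.0051 without spleen library 2 and -0.13 without islet library 2, with 0.27 as the highest with 1 library left out. Cd74 was at -0.43 in limma-voom, and Jchain at -4.30 without islet library 2, the only islet library rich in it, with 4.04 as the highest with 1 library left out. Without spleen library 1, which held most of these transcripts among spleen libraries, H2-Aa was at 2.19 in edgeR and 2.17 in DESeq2, and H2-Eb1 at 1.88 and 1.85. The lowest with 1 library left out were -2.18 and -2.45. With library weights they were at 2.12 and 2.13, and H2-Aa was at 0.0033 in limma on log2(FPKM + 1), 0.0033 there without a filter, and 0.029 with a pseudocount of 5. The macrophage list turned to 0.73 without islet library 1, with -0.63 as the lowest with 1 library left out. The median of all genes was 0.13 with TMM, 0.45 with library size only, 0.07 with upper-quartile scaling and 0.15 with DESeq2 size factors. Depth limits statements on genes near the floor of 0.235 to 0.727 CPM.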

Other observations

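Tests of the splits with all 7 libraries, of spleen library 1 alone, of other cell types and of scaling were chosen after the result had been seen. Cytokine genes moved in both directions. Il10, Gzmm, Pkm and Hspa1a were picked after their values had been seen. Adjusted over the list of chemokines and cytokines alone, Il10 and Xcl1 rose and Ltb and Ccl5 fell. Il10 and Ltb also passed with each library left out in turn. Xcl1 passed without spleen library 1 or islet library 1 but not without any 1 of the others, and Ccl5 did not pass without islet library 3. Il10, the anti-inflammatory cytokine, had 2 fragments in the spleen libraries and 29.4, 6.98 and 4.02 CPM in islet. Xcl1, a chemokine that attracts cross-presenting dendritic cells, averaged 78.2 ± 18.1 CPM in spleen and 370.5 ± 358 CPM in islet, with 772 CPM in islet library 2 and 170.0 ± 120.1 CPM in islet without it. Ccl5, the most abundant of them, averaged 15482 ± 4370.1 and 7437 ± 2122 CPM, and Ltb, a subunit of lymphotoxin, 1359 ± 114 and 387 ± 75.4 CPM. Without spleen library 1, edgeR called Ltb over all genes (adjusted p = 0.0381, with 2.49e-06 to 0.289 over its alternatives). The list itself was not called (adjusted p = 0.408), with a median of -0.70 and a mean of 0.18.

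Among glycolysis genes, Ldha and Pkm, which act at its last steps, rose when adjusted over the list alone. The number rising was 5 without spleen library 1, 1 without islet library 1, which was Ldha, and 0 without any 1 of the other libraries. Ldha averaged 914 ± 174 CPM in spleen and 2045 ± 292 CPM in islet, and Pkm 137 ± 62.5 and 556 ± 207 CPM. The list was not called with all 7 libraries (camera adjusted p = 0.110) and was called without spleen library 1 (adjusted p = 0.0144, with 0.00330 to 0.656 over its alternatives). The remaining lists were not called with all 7 libraries: respiratory chain (adjusted p = 0.110, with 0.00469 to 0.908 over its alternatives), MHC class I (0.0916, with 0.00688 to 0.538), type I interferon (0.207), T cell receptor activation (0.515, median -0.08 and mean 0.41), TGF-beta response (0.904), costimulation (0.883), and chemokine receptors and integrins (0.899). In the last of these Itga1 alone rose when adjusted over the list, but not without islet library 1, 2 or 3. By mean log2 CPM, the glycolysis, activation, and chemokine receptor and integrin lists were higher in every islet library than in any spleen library. For each the exact two-sided permutation p was 0.0571, the smallest possible. It was 0.114 to 0.914 for the other lists of this paragraph that were not called. Cd69 fell over the activation list alone, but not without spleen library 2, spleen library 4, islet library 1 or islet library 3, and without spleen library 1 or 3 the number falling was 2. Lists with under 5 tested members were not tested: beta cell (2), other endocrine (0), acinar (2), ductal (2), B and plasma cell (3), CD4 and regulatory T cell (3), granulocyte, platelet and erythroid (1), and stroma (2). Muc1 rose over the 2 ductal genes alone, but not without spleen library 2, spleen library 4 or islet library 1.

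Chance was examined by refitting all 35 splits of the 7 libraries. Camera called 9 lists for the real split, and 2 of the 35 splits gave as many, with 9 as the highest of the others, so chance is not excluded by this count. DESeq2 called 401 genes for the real split, and 4 of the 35 splits gave as many, with 690 as the highest of the others. The 3 others each put spleen library 1 and 2 more spleen libraries against the rest, and so keep much of the tissue difference. Splits with both tissues on each side gave 0 to 21 genes in DESeq2. Such splits hold the tissue difference as spread within each side, so they do not give the rate of false calls. EdgeR called 0 genes in each of the 35 splits. Without spleen library 1 it called 80 for the real split and 0 in the other 9 of 10, of which 1 gave as many, but 10 splits are too few for a share under 0.05.

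The higher cell cycle genes in islet are the first pattern. In 3 of the 35 splits their median was at least as large in size as the 4.25 of the real split, with 4.87 as the highest other, so chance is not excluded by size alone. Both other splits set 3 spleen libraries against the rest, and with the sign kept the highest other was 1.35. Poorer detection in spleen is argued against, since the median lay above 100% of 10000 random lists matched on islet level, the highest of which reached 0.80. Spleen library 1 is not the cause, as the median without it was 4.40. Dividing cells of another type are not excluded. The highest median level among lists of other cells was 3.91 CPM, for macrophages, against 126 CPM for the cycle genes. That median covers all markers of a list and can stay low where single markers are high. Jchain had an islet mean of 473 CPM. No list covered CD8 T cells of another specificity. Macrophages and plasma cells as the main source are argued against by islet library 1, nearly free of Apoe and Jchain. Its cycle level was as high as in the others. More division among IGRP-specific cells in islets is a hypothesis that stays open, along with pooling and any difference in handling between tissues, which cannot be told apart from tissue here.

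The second pattern is the lower ribosomal protein genes. Scaling as the whole cause is argued against, since the median itself ranged from -1.51 to -0.90 under the other scalings, against -1.25 with TMM, and spleen library 1 alone is too, with -1.07 without it. Transcript length stays open. Of 10000 random lists chosen for similar length and level, 0% had a median as low and their typical median was -0.60, but the match missed: those genes were longer (0.231 against 0.172 of the median gene) and less abundant (1081 against 3060 CPM). A difference in RNA handling or library preparation between tissues stays open, as does a biological one, and neither was tested.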
